A study of Mus musculus with 6 samples.

How the data were processed

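Each of the 6 arrays measured total RNA from 1 frontal cortical lobe of a mouse aged 21 days, extracted with RNA-Stat60 and made into biotinylated cRNA with the 3' IVT PLUS kit, per the labels' protocols. The deposited values are array signal intensities on a linear scale for 45101 probe sets, made with Affymetrix Expression Console and MAS5, per the submitters' processing notes. Versions are not given in the sources used here. From the values themselves, the mean without control probe sets, after trimming 2% at each end, was 249.4 to 249.5 on every array. The 27 bacterial control probe sets, which match nothing in a mouse, read at most 28.4 to 39.6 per array and serve as a measure of background. Probe sets far below this are bounds more than levels. The ratio of 5' to 3' control signal was 1.37 to 1.43 for Gapdh and 0.688 to 0.757 for Actb.

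Probe sets were named from the platform annotation: 34958 named 1 gene, 932 named several and 9211 are unnamed here. Gene IDs were matched to RefSeq's gene table for the mouse assembly for 34754 probe sets, and 0 symbols changed. That table served only for names and for which genes neighbour each other, and no coordinates are given because the sources used here name no build. Each gene took its probe set with the highest mean signal, leaving those ending in _x_at for last. Of 18194 genes, 11499 whose probe set had a mean signal of at least 89.0, the median over probe sets, were kept. Signals were analysed as log2(signal + 28.1), where 28.1 is the 25th percentile of all values. Fold changes are on that scale and understate changes of dim genes.

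The groups are the genotypes in the labels. The 3 reeler models were compared with the 3 comparison arrays by limma 3.58.1 in R 4.3.3, with a trended empirical Bayes prior and Benjamini-Hochberg adjustment over all kept genes. Arrays of a class differ in genotype, so the residual spread holds genotype differences too. The procedure was tested on simulated data of 11499 genes. Of 200 changed genes it recovered 83.0% at 2-fold and 96.5% at 4-fold, with 10 false calls each, and it made 0 calls with no change. The simulated genes varied independently and shared no effect of an array. Real arrays need not meet this, so these rates may not carry over. Gene lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, with adjustment over the lists. There were 27 lists fixed before the data were examined, of which 25 had the minimum of 4 kept genes. The blood list kept 3 and the sex list 1. A further 6 lists were put together after the values had been seen, and their results are adjusted over those 6. The pituitary list and the list of other organs were tested with 3 kept genes each, below the minimum set for the fixed lists. With 1 array per genotype, each mutant against WT and the double against the single knockouts are described by log2 differences with no p-value, and list medians by their percentile among 10000 random lists of the same size, matched on mean expression in 20 bins. Agreement between mutants was set against simulated arrays that share the WT array and have no difference put in. Their spread was the residual SD of the class comparison.

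The genes named in the text follow a rule fixed at the same time as the lists. It takes the targeted genes and genes of sex, all genes past an adjusted p of 0.05 in the class comparison if at most 24, filled up to 24 with the highest and lowest genes without overlap. It also takes the 5 highest and 5 lowest genes of each mutant, the 3 highest and 3 lowest departures of the double knockout, and the 2 highest and 2 lowest members of each list described. The genes higher in every mutant, the examples among genes 2-fold from WT in all reeler models, Neurod1 on the single arrays, members of the lists made later, Ttr, and hormone genes other than Gh were chosen after their values were seen. Alternatives were a pseudocount of 1 or of 89.4, no filter, a filter at 297.5, quantile normalization, the mean of all probe sets of a gene, no trend, all probe sets, a cross covariate, other choices of comparison array and leaving out each array in turn.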

Results

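Gene expression was measured on 6 microarrays, each labelled as a frontal cortical lobe of a mouse aged 21 days. The mice were on a mixed C57BL/6 and 129 background. Genes of the cerebellum, hypothalamus and choroid plexus also gave signal on every array, so the samples may hold more than that lobe. There was 1 array per genotype. The receptor cross gave a wild type (WT), a Vldlr knockout, an Apoer2 knockout and a knockout of both receptors. A Dab1 knockout and a Reln knockout came from crosses of their own. Reelin, encoded by Reln, is a secreted protein that guides the placement of cortical and cerebellar neurons. Vldlr and Apoer2 (gene symbol Lrp8) are its receptors, and Dab1 is the adaptor that carries the signal inside the cell. The Dab1, Reln and double receptor knockouts are called reeler models here, after the series title, and the WT and the single receptor knockouts are the comparison arrays. Median signals were 86.5 to 92.3 across arrays and Pearson's r of log2 signals between arrays, over genes, was 0.955 to 0.982. No genotype had a replicate, so the number of arrays limits the precision of every value. The p-values below treat arrays of different genotypes in a class as replicates and measure only the spread between these 6 arrays.

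The first question was whether each array showed the loss of its targeted gene. Reln signal was 79.9 on the Reln knockout array at its brightest probe set, against 1498 to 1880 on the other 5 arrays. At Lrp8, the brightest probe set read 4.2 on the Apoer2 knockout array and 13.7 on the double knockout array, against 342.4 to 379.8 elsewhere. At Vldlr, the probe set used for the gene read 187.3 on the Vldlr knockout array and 185.6 on the double knockout array, against 357.6 to 551.6 elsewhere. Dab1 differed less: over its 5 probe sets the Dab1 knockout array differed from WT by -0.25 to -0.73 on the log2 scale, with 478.5 against 576.2 at the brightest and 102.1 against 187.8 at the dimmest. The Dab1 knockout array was lowest at 4 of the 5 Dab1 probe sets. At the remaining one it read 299.8, above the Apoer2 (233.0), Vldlr (236.8) and double (298.0) knockout arrays. All 6 Vldlr probe sets read lower than WT on both arrays that lack Vldlr, with log2 differences from -0.57 to -1.82. The dimmest Lrp8 probe set differed by only -0.50 and -0.48 on the arrays that lack Apoer2. The labels used here do not give the deleted part of any gene, and a probe set outside it checks nothing.

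**Figure D1:**
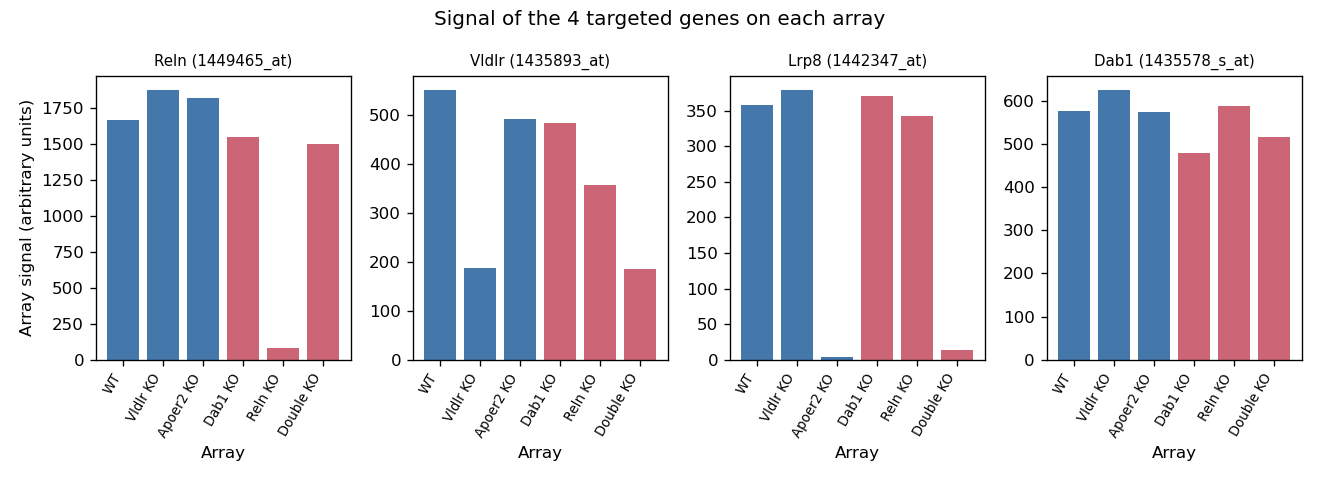
Array signal (vertical axis, arbitrary units, starting at 0) of Reln, Vldlr, Lrp8 and Dab1 at the probe set used for each gene, 1 bar per array, with comparison arrays in blue and reeler models in red. Reln was 79.9 on the Reln knockout array, Lrp8 4.2 and 13.7 on the Apoer2 and double knockout arrays, and Dab1 478.5 on the Dab1 knockout array against 576.2 on the WT array.

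Genes that mark sex did not follow the labels, which call every animal male. Xist, the RNA that silences an X chromosome in females, read 3368 to 4006 on 5 arrays at its brightest probe set and 124.9 on the Apoer2 knockout array. The Y-linked genes Eif2s3y (367.5), Uty (186.2) and Kdm5d (125.7) were bright only on the Apoer2 knockout array at their brightest probe sets there, where the other 5 arrays read at most 7.7, 19.2 and 32.0. The Apoer2 knockout array also read 3705 for Gh, growth hormone, against 13.1 to 32.4 elsewhere.

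The reeler models were then set against the comparison arrays to ask which transcripts all 3 models shared. Genes of cerebellar granule cells dominated the lower side. Fat2, a protocadherin of granule cells, fell by 3.21 on the log2 scale (SE 0.36, 9.27-fold lower, adjusted p = 0.0105), and Gabra6, a granule cell subunit of the GABA-A receptor, fell by 3.07 (SE 0.26, 8.39-fold lower, adjusted p = 0.00571). The cerebellins Cbln3 and Cbln1, which organise synapses, were 6.69-fold and 2.66-fold lower. Neurod1 (3.78-fold), En2 (3.18-fold) and Zic1 (3.09-fold), transcription factors of the cerebellum and hindbrain, also fell, as did the NMDA receptor subunit gene Grin2c (2.22-fold). On the higher side stood Galc, the lysosomal enzyme that degrades myelin galactolipid (4.12-fold, adjusted p = 0.00140), and Agt, angiotensinogen (1.81-fold, adjusted p = 0.0329). Agt no longer passed with no filter, with no trend, or when the WT array or the Vldlr, Dab1, Reln or double knockout array was left out.

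In all, 15 of 11499 genes passed an adjusted p of 0.05 in limma, 2 higher and 13 lower, and every one of them had its 3 reeler arrays on 1 side of the 3 comparison arrays. The other lower genes were Cnpy1 (5.36-fold), the corepressor gene Rcor2 (4.19-fold) and the cytokine gene Il16 (2.71-fold). Chn2 (2.02-fold), which encodes a Rac regulator, and Fgf14 (1.63-fold), which encodes a sodium channel modulator, fell too. Whether these genes also mark cerebellar cells was not tested. At an unadjusted limma p of 0.05 there were 601 higher and 668 lower genes, 1269 in all. Other groupings of the arrays into 3 and 3 gave 239 to 833. The classes did not overlap for 17.7% of genes, against a mean of 10% over all groupings. Genes vary together, so a single grouping can lie above that mean by chance. The rule for named genes also takes the highest genes without overlap. Of these, Plin4 (log2 difference 1.25, adjusted p = 0.348), Gm14198 (1.18, 0.139), Fndc9 (1.11, 0.397), Fkbp5 (1.07, 0.25), 1810021B22Rik (1.06, 0.259), Acot2 (1.0, 0.259), Klhl40 (0.95, 0.356), Rac3 (0.93, 0.106) and Sh3bp1 (0.91, 0.351) did not pass. Probe sets disagreed for Galc: a second one past the signal filter had a log2 difference of -0.31, against 2.04 at the one used. A probe set below the filter also ran the other way for Acot2 (-0.27). Further probe sets ran the same way for Il16 (-1.55 and -0.48) and Fkbp5 (0.77), and each of these genes has 1 more at background level, whose direction (0.15 and -0.015) decides nothing. The other filter-passing probe sets of Cbln1, Cbln3, Chn2, Cnpy1, Fgf14, Gabra6, Neurod1 and Zic1 were lower too. Without the WT array 1 gene passed, with WT as the only comparison array 0 did (the direction of all 15 was kept), and without the Dab1 knockout array 22 did. The Dab1 and Reln knockouts have no comparison array from their own crosses. With the receptor cross against the other crosses as a covariate, the class difference therefore rests on the double knockout array alone against the 3 comparison arrays. It kept the direction of all 15 genes but does not check an effect shared by the reeler models.

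**Figure D2:**
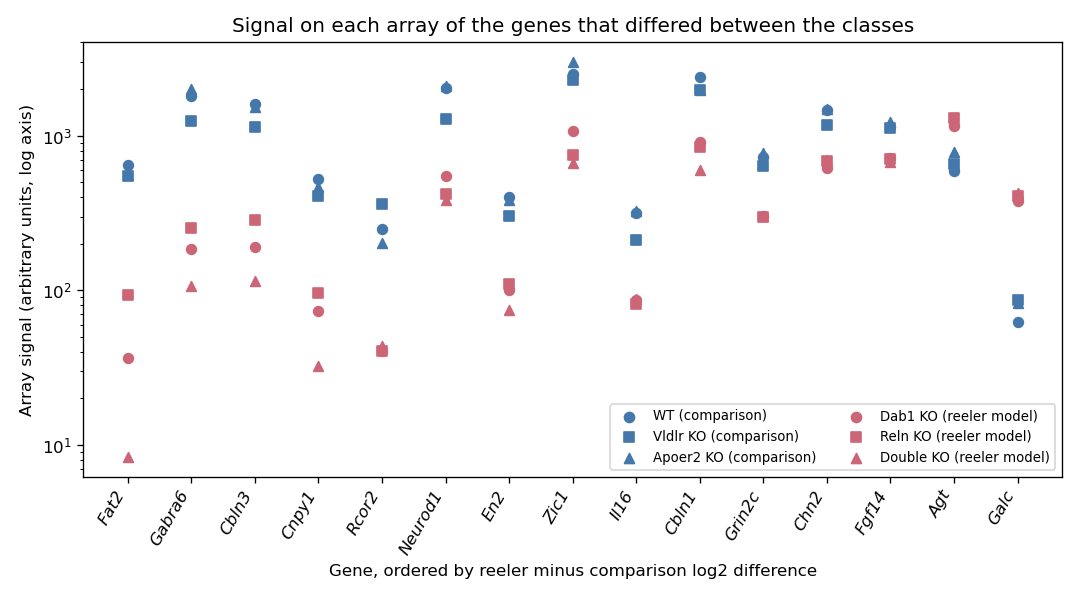
Signal on each of the 6 arrays (vertical log axis, arbitrary units) of the 15 genes past an adjusted p of 0.05, ordered along the horizontal axis by their log2 difference, with comparison arrays in blue and reeler models in red. Each gene's 3 reeler arrays lie on 1 side of its 3 comparison arrays, as for Gabra6, with 106.6 to 251.5 against 1248 to 2015.

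Because granule cell genes led this comparison, lists of granule and Purkinje cell genes were put together after the values had been seen. All 14 granule cell genes past the signal filter were lower in the reeler models, with a median log2 difference of -1.28. Of these, 8 passed over all genes and 13 adjusted over the list alone, and members that did not pass over all genes included Grm4 (-0.92), Cadps2 (-0.98) and Gabrd (-0.90). The list passed limma's camera test (adjusted p = 2.36e-28), and with an estimated correlation the adjusted p = 0.0192. Without the Reln knockout array the median was -1.31 and that call was lost (adjusted p = 0.0959 with an estimated correlation). Having been chosen on these arrays, this list is no independent evidence. The 8 genes past the signal filter of Purkinje cells, the output neurons of the cerebellar cortex, had a median of -0.16 (adjusted p = 0.217). Against WT, the granule median was -1.19, -1.44 and -1.59 on the Dab1, Reln and double knockout arrays and -0.24 and -0.06 on the Vldlr and Apoer2 knockout arrays. The mean log2 signal of granule genes minus that of Purkinje genes was -1.68 ± 0.05 (SD, n = 3) in reeler models and -0.30 ± 0.21 in comparison arrays. A two-sided exact permutation test gave p = 0.1, the lowest that 3 arrays against 3 can give.

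**Figure D3:**
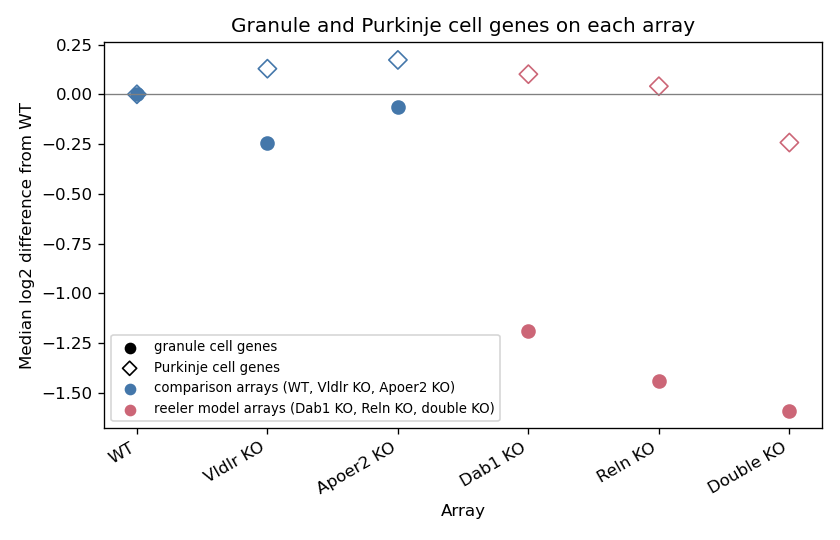
Median log2 difference from the WT array (vertical axis) of 14 granule cell genes (filled circles) and 8 Purkinje cell genes (open diamonds) on each array, with comparison arrays in blue and reeler models in red. The granule medians of the reeler models lie between -1.19 and -1.59, and their Purkinje medians between -0.24 and 0.10.

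Gene lists fixed before the data were examined were tested in the same contrast. Of 25 tested lists, 1 was shifted up and 4 down by camera, and none of these calls held with an estimated correlation. Mitochondrial respiration genes were shifted up by a small amount (18 genes, all above 0, median log2 difference 0.12, adjusted p = 0.000194, and adjusted p = 0.504 with an estimated correlation), led by Uqcrc1 (0.26) and Vdac1 (0.24), with Ndufa1 at 0.02 and Cyc1 at 0.0025. None of its 18 genes passed over all genes or adjusted over the list alone. Receptors for glutamate and GABA were shifted down (20 genes, median -0.15, adjusted p = 0.00187, and 0.504 as the adjusted p with an estimated correlation). The median was -0.058 without the Reln and -0.079 without the Vldlr knockout array, and -0.21 to -0.15 without any other single array. Grin2c passed over all genes, and 4 lower and 1 higher genes passed adjusted over the list alone. Its lowest members, Grin2c (-1.15) and Gabrd (-0.90), are both granule cell receptor subunits, and its highest were Gabra3 (0.39) and Gabra5 (0.25).

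Interferon response genes were shifted down (8 genes, median -0.29, adjusted p = 0.00742, and adjusted p = 0.504 with an estimated correlation). None passed over all genes, and 1 did adjusted over the list alone. Ifit3 (-0.93) and Ifi27 (-0.52) were lowest, and Rsad2 (0.20) and H2-K1 (-0.14) highest. Meningeal and fibroblast genes were shifted down (11 genes, median -0.29, adjusted p = 0.00827, and adjusted p = 0.504 with an estimated correlation), with the collagen genes Col1a1 (-0.61) and Col3a1 (-0.44) lowest and Aldh1a2 (0.13) and Ptgds (0.07) highest. Heat shock and stress genes were shifted down (15 genes, median -0.17, adjusted p = 0.00840, and adjusted p = 0.679 with an estimated correlation). The lowest were Sdf2l1 (-0.57) and Xbp1 (-0.33), of the endoplasmic reticulum stress response, and the highest the small heat shock gene Hspb1 (0.28) and Hspa1b (0.17). For the meningeal and the heat shock lists, 0 genes passed over all genes and 0 adjusted over the list alone. Call by call, quantile normalization ended the mitochondrial shift (adjusted p = 0.454), the cross covariate the interferon shift (0.350), and a stricter filter (0.0641) or the mean of all probe sets (0.127) the meningeal shift. The receptor shift was lost without the Vldlr knockout array (0.0928) or with WT alone (0.134), the interferon shift without the Dab1 knockout array (0.0677), and the heat shock shift without the WT (0.119) or the Dab1 knockout array (0.140). Over all alternatives the adjusted p ran from 1.56e-07 to 0.454 for mitochondrial respiration, 0.000160 to 0.134 for receptors, 0.000354 to 0.350 for interferon, 0.00126 to 0.127 for meninges and 2.87e-05 to 0.140 for heat shock.

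Cortical layer genes did not pass the test, which measures RNA amounts in a whole sample and not where in the cortex cells lie. Genes of other brain regions also gave signal on these arrays, so a lack of change in cortical layers is not shown. The 17 upper-layer genes had a median log2 difference of 0.09 (adjusted p = 0.398), between Cux2 (0.53) and Cdh13 (0.33) at the top and Lhx2 (-0.27) and Pou3f2 (-0.26) at the bottom. The 24 deep-layer and subplate genes had a median of 0.04 (adjusted p = 0.951), with Ccn2 (0.56) and Sulf2 (0.34) highest and Nr4a2 (-0.57) and Moxd1 (-0.33) lowest. In both lists 0 genes passed over all genes and 0 adjusted over the list alone. Among 20 interneuron genes (median 0.14, adjusted p = 0.0633) none passed over all genes, and 3 higher and 2 lower did adjusted over the list alone. Npy (0.54) and Gad2 (0.43) were highest and Calb2 (-0.47) and Pvalb (-0.31) lowest. The 32 genes of the reelin pathway list had a median of -0.01 (adjusted p = 0.990), with Gsk3b (0.34) and Src (0.30) at the top and Reln (-1.51) and Itga3 (-0.26) at the bottom, and 0 passed over all genes or over the list alone. Astrocyte genes (16, median -0.03, adjusted p = 0.127) included 1 lower gene adjusted over the list alone, and myelin genes (16, median -0.03, adjusted p = 0.342) had 0. Immediate early genes, induced by neuronal activity, had a median of 0.32 (18 genes, adjusted p = 0.0633), with Arc (1.09) and Npas4 (0.87) highest and Nr4a3 (-0.84) and Homer1 (-0.13) lowest.

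Among the lists that did not pass, those holding a cerebellar gene carried the only members past the threshold. The thalamus list (9 genes, adjusted p = 0.0633) held Zic1, and the lists of excitatory neurons (14 genes) and of immature neurons (13 genes, both with an adjusted p = 0.990) held Neurod1. No member passed over all genes in the lists of sterol synthesis (adjusted p = 0.0887), endothelium (0.127), circadian clock (0.342), hippocampus (0.347), presynaptic vesicles (0.472), microglia (0.486), olfactory bulb (0.560), striatum (0.574), choroid plexus (0.951) and oligodendrocyte precursors (0.966). Adjusted over the list alone, 2 lower genes passed in the thalamus list, 1 lower gene each in those of excitatory neurons, immature neurons and olfactory bulb, and 1 higher gene in that of the striatum. Median, mean and test direction differed in sign for the lists of thalamus (median 0.0009, mean -0.24), excitatory neurons, immature neurons, presynaptic vesicles, striatum, choroid plexus and the reelin pathway.

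Each mutant was also described against the WT array, with no test. The Reln knockout array stood furthest away, with 133 genes at least 2-fold higher and 153 at least 2-fold lower. The Dab1 knockout array had 33 higher and 86 lower genes, the double knockout 39 and 68, the Vldlr knockout 28 and 55, and the Apoer2 knockout 23 and 22. The balance of higher and lower genes depended on the processing for 3 arrays: the Reln knockout had 78 higher and 62 lower genes with the median as pseudocount, 147 and 139 with quantile normalization and 290 and 283 with no filter, the double knockout 201 and 185 with no filter, and the Apoer2 knockout 44 and 46 with a pseudocount of 1. On the Reln knockout array, Reln itself was 15.7-fold lower, followed by 4933439C10Rik (10.8-fold), Gabra6 (6.53-fold), Pdxdc1 (5.87-fold) and Pttg1 (5.69-fold). Highest were Ctla2a (5.91-fold), the lipid droplet gene Plin4 (5.73-fold), Fndc9 (5.20-fold), Dpm3 (5.06-fold) and Galc (4.79-fold). On the Dab1 knockout array the lowest were Fat2 (10.4-fold), Snhg14 (9.63-fold), Efhd2 (8.63-fold), Gabra6 (8.54-fold) and Cbln3 (7.39-fold). The highest were Galc (4.48-fold), Gm14198 (3.78-fold), Cd33 (3.74-fold), 9630013A20Rik (3.44-fold) and Foxh1 (2.84-fold).

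On the double knockout array the lowest genes were Fat2 (18.4-fold), Gabra6 (13.5-fold), Cbln3 (11.4-fold), Serpina3n (9.63-fold) and Lrp8 (9.23-fold), and the highest were Pam (5.13-fold), Tent5c (5.13-fold), Galc (5.02-fold), the erythroid gene Alas2 (4.73-fold) and Khsrp (3.64-fold). On the Vldlr knockout array Tmem87a (7.88-fold), Cap1 (6.40-fold), Efhd2 (5.64-fold), Pttg1 (5.45-fold) and Mid1 (4.20-fold) were lowest, and Gdpd3 (5.97-fold), Khsrp (4.04-fold), Gm35161 (3.59-fold), 2810049E08Rik (3.16-fold) and Foxh1 (2.97-fold) highest. On the Apoer2 knockout array Gh was 77.0-fold higher, followed by Pam (4.37-fold), Gdpd3 (3.14-fold), Cd33 (2.74-fold) and the activity-induced gene Arc (2.60-fold). The lowest there were Xist (23.0-fold), Lrp8 (11.9-fold), Pttg1 (7.75-fold), Ap4m1 (4.62-fold) and Il6ra (3.85-fold). The WT array itself stood apart for 5 genes that were at least 2-fold higher in every mutant: 2810049E08Rik, Cd33, Foxh1, Gm35161 and Sf3b3. Against the mean of the 3 comparison arrays, 71, 175 and 60 genes differed by 2-fold or more on the Dab1, Reln and double knockout arrays, in place of 119, 286 and 107 against WT.

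The fixed lists were placed, array by array, among 10000 random lists of like size and expression. Immediate early genes had a median log2 difference from WT of 0.78 on the Reln, 0.62 on the Apoer2 and 0.43 on the double knockout array, all above every random list, and of -0.31 on the Vldlr knockout array, below every one. Arc ranged from -1.75 on the Vldlr to 2.26 on the Reln knockout array. Immature neuron genes stood above every random list on the Vldlr (0.45) and Dab1 (0.49) knockout arrays, although Neurod1, a member, was -0.67 and -1.84 from WT there. Dpysl3 (0.71) and Tubb2b (0.70) were highest on the Vldlr and Marcksl1 (0.91) and Dcx (0.86) on the Dab1 knockout array. Myelin genes were below every random list on the Vldlr (-0.28), Apoer2 (-0.11), Dab1 (-0.35) and Reln (-0.37) knockout arrays. On the double knockout array their median was -0.024, at the 1.62nd percentile. Cryab, a chaperone of oligodendrocytes, was the lowest member on every mutant array, from -0.92 on the Apoer2 to -1.43 on the Reln knockout array. Heat shock genes were below every random list on the Vldlr (-0.34), Dab1 (-0.46) and double (-0.39) knockout arrays, and interferon response genes were lowest on the Dab1 knockout array (-0.74). Upper-layer neuron genes were at the 99.9th percentile on the double knockout array (0.25). They were also high on the Vldlr (0.16, percentile 99.2), Dab1 (0.17, 98.3) and Apoer2 (0.11, 97.1) knockout arrays, but not on the Reln knockout array (-0.03, 33.7). Deep-layer genes were at the 99.97th percentile on the Vldlr (0.19) and the 97.7th on the Dab1 knockout array (0.12). On the Apoer2, double and Reln knockout arrays they were at percentiles 89.2, 84.4 and 53.3. Between 8 and 11 of the 25 lists lay outside the central 95% of random lists on each array. For lists of unrelated genes, 0.625 would be outside on each side. Members of a fixed list can vary together (estimated correlation 0.56 for immature neurons), so unchanged arrays could place more lists outside, and this count measures no excess. These percentiles describe pairs of arrays and not genotypes, and every pair shares the WT array.

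**Figure D4:**
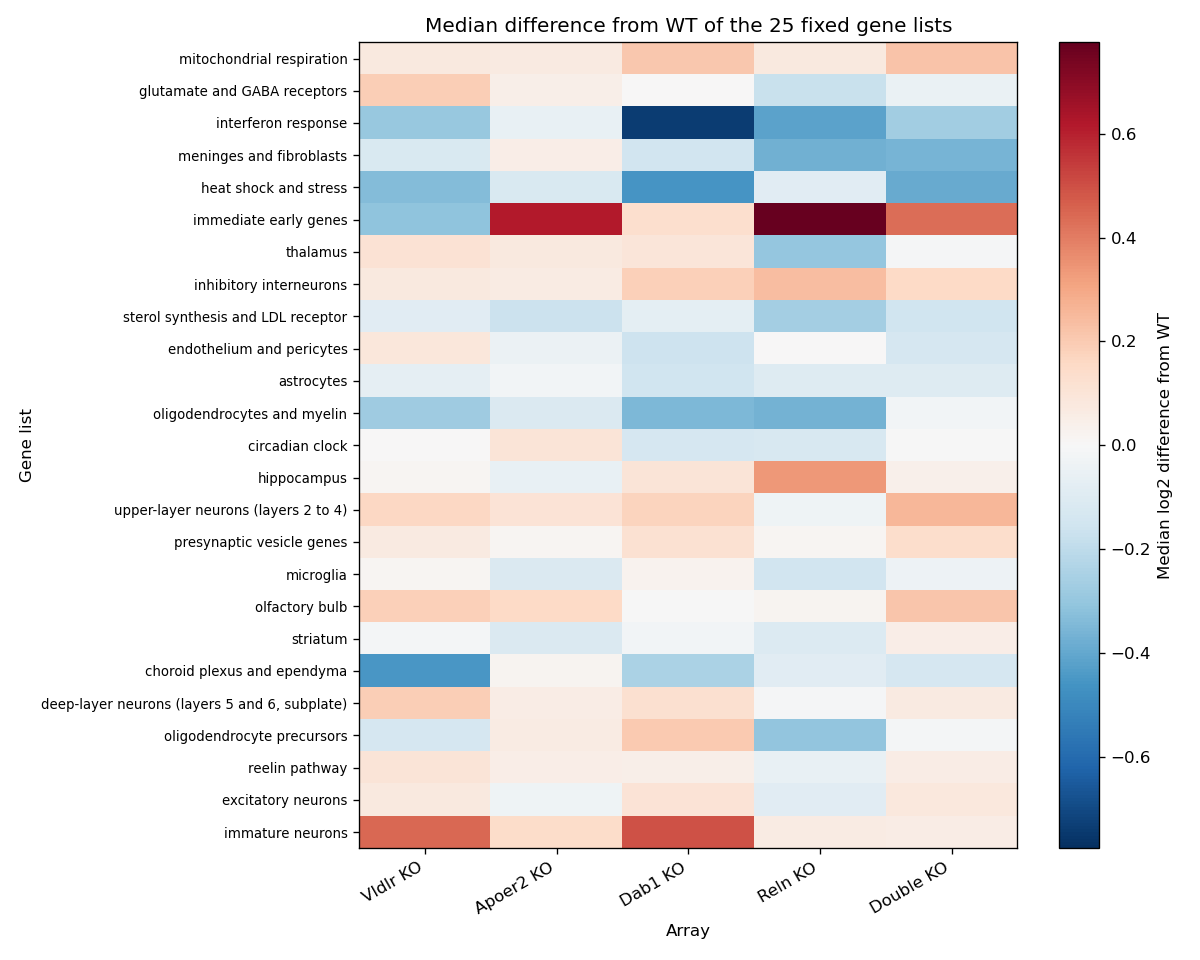
Median log2 difference from the WT array (colour, red higher and blue lower) of the 25 fixed gene lists (rows) on the 5 mutant arrays (columns). Immediate early genes reach 0.78 on the Reln knockout array and -0.31 on the Vldlr knockout array, and interferon response genes -0.74 on the Dab1 knockout array.

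Because the reeler models lack the ligand, both receptors or the adaptor of 1 pathway, the agreement of their changes was measured. Among genes at least 2-fold from WT on all 3 reeler arrays, 21 were lower and 11 higher. The lower ones included Gabra6, Cbln3, Fat2, Neurod1 and Zic1, and the higher ones Galc, Cd33 and Foxh1. Of the 11 higher genes, 5, among them Cd33 and Foxh1, were higher in the single knockouts too. Arrays simulated with no difference put in, against 1 shared WT array, gave 9.04 lower and 8.86 higher genes. Independent lists would share 0.00677 and 0.00129. The simulated spread was the residual SD within the classes, which holds genotype differences too, so these arrays are not strictly unchanged. Over all genes, Pearson's r between mutants was highest for the Dab1 and double knockouts (r = 0.64, Spearman's rho = 0.63), where the simulation gave 0.50 and 0.46. Their covariance was 0.0662 against 0.0440 simulated. It was 0.0726 for the Reln and double knockouts, 0.0648 for the Dab1 and Reln knockouts and 0.0325 for the Vldlr and Apoer2 knockouts. By covariance the 3 reeler pairs were the highest of all pairs, with the Vldlr and Dab1 knockouts next (0.0557). By r the order differed, with 0.60 for the Vldlr and Dab1 knockouts against 0.51 for the Dab1 and Reln knockouts. The simulated covariance lay above that of every pair with the Apoer2 knockout (0.0325 to 0.0374), so the simulation is no exact baseline. Part of the excess over it may come from the shared WT array. With each reeler model paired to a different comparison array, the mean r was 0.19 (range 0.04 to 0.33), and the highest among the 9 other groupings of the arrays was 0.06. These correlations are across genes, which are not independent replicates.

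Within the receptor cross, the double knockout was set against the sum of both single knockouts. Fat2, the protocadherin of granule cells, was among the genes furthest from that sum. It was -4.20 from WT in the double knockout, against -0.22 in the Vldlr and -0.19 in the Apoer2 knockout. Among all genes, 183 departed from the sum by 1 or more on the log2 scale, 94 above and 89 below. The furthest above were Xist (4.59), Ap4m1 (2.67) and Cap1 (2.64), and the furthest below Gh (-6.62), Gdpd3 (-4.89) and Fat2 (-3.79). Xist and Gh depart because of the Apoer2 knockout array alone, where Xist was -4.53 and Gh 6.27 from WT. Cap1 was -2.68 from WT in the Vldlr knockout and 0.71 in the double knockout. With 4 arrays and 4 genotypes there are no degrees of freedom for a test. Across genes, the double knockout difference correlated with the sum at r = 0.60, with all 3 differences sharing the WT array.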

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

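All tests of explanations in this part were chosen after the results had been seen, except the count of gene lists over other groupings of the arrays.

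Genes of cerebellar granule cells were lower in the 3 reeler models. Less cerebellum in those samples would lower Purkinje cell genes about as much, if those genes were read from cerebellum alone, which was not tested. The Purkinje median was -0.16, where the granule median was -1.28 and the bound set for this explanation -0.64. Under that assumption, this argues against less cerebellum as the whole account. The SE of 0.06 used with that bound is over 8 genes that vary together (estimated correlation 0.41), and not over arrays. From WT the Purkinje median was 0.10, 0.04 and -0.24 on the Dab1, Reln and double knockout arrays. The granule median was -1.19, -1.44 and -1.59 there. On the double knockout array the Purkinje median was at the 0.08th percentile of random lists. Car8 read 1262 there against 2300 on the WT array and Pcp2 1828 against 2336, while Dner read 2904 against 2532. Less cerebellum as part of the change on that array therefore stays open. The Apoer2 knockout array is not the source of the granule pattern, since without it the granule median was -1.27. A granule cell change in each reeler genotype stays open: the reeler array nearest to WT had a granule median of -1.19, but the list was chosen on these arrays and cannot bear the pattern out, and a dissection that took different layers of the cerebellum was not tested. The class comparison called 15 genes and the highest of the 9 other groupings 1, so 1 of the 10 groupings gave as many. The 10 groupings are too few for a share under 0.05, and the same holds for the 5 called lists, where 6 of the 10 groupings gave as many and the highest other gave 9.

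The Apoer2 knockout array alone carried Y-linked genes and Gh. Loss of Apoer2 as the reason for Gh is argued against by the double knockout, where Gh differed from WT by -0.24. A wrong genotype label is argued against by Lrp8: of its probe sets that fall in the double knockout, the one nearest to WT was still -3.25 from it on that array. Pituitary tissue in that sample stays open: 3 of 8 pituitary genes were highest there by 1 log2 unit or more, but Gh had prompted the test. With Gh left out 2 of 7, Prl (192.6 against at most 50.2) and Cga (109.5 against at most 14.7), fell short of the 3 set as the bound. Pomc was also highest there (341.3 against at most 162.2), but by 0.957 log2 units, just under the 1 needed to count. Lhb, Fshb, Tshb and Ghrhr were not highest there. Male tissue as 50% or more of the other 5 samples, which are labelled male, is argued against by Eif2s3y, Uty and Kdm5d. These Y-linked genes read at most 25.5% of their signal on the Apoer2 knockout array. The 25.5% is a bound: Kdm5d read 32.0 on the WT array, where bacterial controls reached 35.2. With Xist at 3368 to 4006, these values argue against the male label of those 5 samples. How label and sample came to differ was not tested.

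Galc was 4.12-fold higher in the reeler models at its brightest probe set. A rise of the whole transcript is argued against by the other Galc probe set past the filter, which differed by -0.31 (SE 0.15). A change confined to part of the transcript, or a strain variant under the probe set, stays open and was not tested.

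For 9 of the 91 genes named by the rule, against 3.84% of all genes, every reeler array moved from WT in the opposite direction to both single receptor knockouts, and that difference was not tested. Sh3bp1 was 0.30 to 1.29 from WT in the reeler models and -0.69 to -0.05 in the single knockouts, a difference of means of 1.03. Gdpd3 was -1.04 to -0.22 against 1.65 to 2.58, a difference of -2.75. Reln was -3.97 to -0.11 against 0.12 to 0.17, a difference of -1.56 that rests on the Reln knockout array. The same held, with smaller differences of means, for Nr4a3 (-0.998), Nr4a2 (-0.66), Col3a1 (-0.52), Calb2 (-0.52), Gad2 (0.45) and Uqcrc1 (0.29). Genes named from the class comparison and the lists were chosen by their difference between the classes, which favours this pattern.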

How the results depend on the processing

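The count without granule genes and the separate test of the lists made later were chosen after seeing the data. No paired analysis was possible because each genotype has 1 array and the groups share no number that pairs them. In the class comparison, the 2 higher genes became 1 with no filter, the stricter filter, the mean of all probe sets, no trend, the cross covariate or no granule genes, and 0 with WT alone. The 13 lower genes became 8 with the cross covariate, 0 with WT alone and 22 probe sets when all probe sets were kept. Without the genes of the granule list they became 5. That list was made after the values were seen and may leave out cerebellar genes. These 5 therefore show no change outside the cerebellum. Leaving out 1 array gave 1 to 2 higher and 0 to 20 lower genes, the lowest without WT and the highest without the Dab1 knockout. With WT alone, that lone array is assumed to vary like the reeler models. With the cross covariate, the class difference rests on the double knockout array alone against the comparison arrays. Lists shifted up, 1 at first, became 0 with quantile normalization and 3 with WT alone, and 1 to 3 without 1 array. Lists shifted down, 4 at first, became 7 with no filter or quantile normalization, and 4 to 6 without 1 array. List medians that no longer passed were 0.032 for mitochondrial respiration (quantile), -0.29 (stricter filter) and -0.13 (mean of probe sets) for meninges, -0.091 for interferon (cross covariate) and -0.022 for receptors (WT alone). Without 1 array they ranged from -0.21 to -0.058 for receptors, -0.28 to -0.12 for heat shock, -0.41 to -0.17 for interferon, -0.31 to -0.18 for meninges and 0.09 to 0.16 for respiration. The interferon list had too few genes for the stricter filter.

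Genes 2-fold from WT, 83, 45, 119, 286 and 107 for the Vldlr, Apoer2, Dab1, Reln and double knockouts, became 143, 90, 189, 402 and 198 with a pseudocount of 1, 32, 16, 49, 140 and 55 with the median as pseudocount, 305, 266, 407, 573 and 386 with no filter and 27, 15, 43, 132 and 39 with the stricter filter. Against the mean of the comparison arrays they became 71, 175 and 60 for the Dab1, Reln and double knockouts. Departures of the double knockout, 183 at first, became 322, 65, 804 and 58 in those 4 settings. Signal over background limits these counts, since no filter adds the dimmest genes. With a pseudocount of 1, Reln was -4.37 in its knockout and Lrp8 -6.11 and -4.61 in the Apoer2 and double knockouts. The mean r without a shared array moved by less than its spread in all 6 settings (0.118 to 0.243). No gene named from the class comparison and no list called in it turned its direction. Other named genes, such as list members, were not followed over these settings. Of the list medians per mutant, 0 of those outside the central 95% of random lists changed sign, and 24 values of the others did. Of the values of genes named from the class comparison, 303 kept their side of the threshold, 58 fell below it and 1 rose above it. Of the list medians per mutant, 322 moved by less than the spread of random lists and 53 by more. Where the alternative does not itself remove genes or arrays, the cause was not tested.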

Other observations

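All tests in this part were chosen after the results had been seen, except the first neighbour count at each locus.

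A list of genes that respond to glucocorticoids was put together after Plin4 and Fkbp5 had been seen among the highest genes, so its values on these arrays are no independent evidence. All 15 members past the signal filter had a positive log2 difference, with a median of 0.41, led by Plin4 (1.25), Fkbp5 (1.07) and Angptl4 (0.78). None passed over all genes, 5 did adjusted over the list alone, and camera gave an adjusted p = 1.91e-07, or an adjusted p = 0.341 with an estimated correlation. The Reln knockout array contributed most: against WT the median was 0.74 there, 0.35 in the double, 0.32 in the Apoer2, 0.27 in the Dab1 and 0.086 in the Vldlr knockout. The medians of the Apoer2 knockout, a comparison array, and the Dab1 knockout, a reeler model, were closer than the spread of random lists. Without the Reln knockout array the median difference between the classes was 0.19 (adjusted p = 5.09e-05, and adjusted p = 0.498 with an estimated correlation).

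Genes known from other brain regions gave signal on every array. All 11 Purkinje cell genes exceeded the highest bacterial control signal (39.6) on all 6 arrays, among them Pcp2 at 1828 to 2817 and Car8 at 1262 to 2300. So did 6 of 8 hypothalamic peptide genes, such as Pmch at 632.4 to 739.7 and Oxt at 739.5 to 1104. Of 17 genes of liver, pancreas, muscle and testis, 4 did, among them Acta1 at 185.6 to 242.2 and Cyp3a11 at 72.7 to 185.0. Signals of that size, such as Hcrt (146.7 to 236.1), Crh (131.6 to 253.4) and Gal (85.4 to 283.9), therefore do not show a tissue. The same holds for the Purkinje cell genes Grid2ip (75.1 to 100.5), Lhx1 (42.9 to 144.4) and Lhx5 (49.3 to 78.0). Ttr, of the choroid plexus, read 5159 to 7724. The labels name the frontal cortical lobe only. The bright genes of other regions argue against samples of that lobe alone, and which tissue was taken was not tested. Hypothalamic genes (6 kept, adjusted p = 0.427), pituitary genes (3 kept, 0.782) and the genes of other organs (3 kept, 0.628) did not pass camera between the classes.

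A hypothesis was that DNA of the 129 strain, linked to a targeted locus, brings its own expression differences. The measure was the share of up to 200 neighbouring genes on each side that differed by 0.5 log2 units or more from the arrays without that mutation, in every array that carries it. At Lrp8 on chromosome 4 it was 8 of 239 genes, 3.35% against 0.539% over all genes, at the 99.8th percentile of all windows (99.843), which is consistent with linked DNA. At Dab1, also on chromosome 4, it was 18 of 238, at the 97.2nd percentile, short of the bound set beforehand. That count included Lrp8 itself, and its reference held the arrays that lack Apoer2. In a version chosen after these values were seen, with targeted genes and the arrays mutated at the other locus left out, Lrp8 had 6 of 238 genes (98.4th percentile) and Dab1 17 of 237 (91.1th percentile). Hypotheses of the same kind at Reln (17 of 174, 70.0th percentile) and Vldlr (2 of 250, 70.7th percentile) met their bound for no excess. Cap1 was 1.18 higher with Lrp8 targeted and 1.10 with Dab1 targeted against all other arrays, but those references hold the Vldlr knockout array, where it was -2.68 from WT.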
